A study of Mus musculus with 13 samples.

How the data were processed

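Chromatin accessibility was measured by ATAC-seq, in which a transposase inserts sequencing adapters into open chromatin, in sorted mouse microglia. The 13 libraries fell into 6 groups defined by the first injection, by treatment with the CSF1R inhibitor BLZ945 or its vehicle, and by the later injection. Each library was a pool of 2 animals with 40000 cells from each, so a replicate here is a pool and not an animal. The pools PBL 3_4 and PBL 4_5 carry the same animal number 4 in their names; whether they share an animal is not given in the sources used here, and they were treated as separate.

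The deposited table holds, for 1 peak set common to all libraries, an expected or estimated count per peak and library, in steps of 0.5, with no normalization by the authors. All values were whole multiples of 0.5, and between 49.1% and 50.1% of the values of a library ended in 0.5. The tool that made the counts is not given in the sources used here. The submitters' processing notes name cutadapt 1.9.1, Bowtie2 2.2.6, SAMtools 1.7, Picard 1.126, bedtools 2.26, MACS2 2.1.1, deepTools 3.3.0, HOMER 4.9.1 and ChIPseeker 1.38 with the builds GRCm38 and mm10, without saying in which order or with which settings they were run. Whether read ends were shifted for the transposase offset is not given there. The table held 38620 peaks, none of which overlapped another, with a median width of 439 bp. Peak widths and the distance of each peak to its nearest transcription start site are in bp, per the file headers. A peak counted as a promoter peak where the deposited annotation called it one, which held for peaks within 1 kb of a start site. A further deposited column gives the isolation date of each library, and another the sorter.

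Counts were rounded to whole numbers and analysed in R 4.3.3 with edgeR 4.0.16. Peaks with low counts were removed with filterByExpr at its minimum count of 10, which left 37516 peaks and removed 1104. Libraries were scaled by TMM factors. A quasi-likelihood model with 6 group means was fitted to all 13 libraries with robust dispersion estimates, each comparison was tested with the quasi-likelihood F test, and p-values were adjusted by the Benjamini-Hochberg method over the tested peaks. A peak was called at an adjusted p under 0.05 with no minimum fold. The SE of a log2 fold change is its absolute value divided by the square root of its F statistic. All tests were two-sided. Levels are given as CPM (counts scaled to a common library total) with the SD over the libraries of a group.

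For gene loci, the counts of all peaks whose nearest start site belonged to the gene and lay within 50 kb were summed, and 13734 loci were tested in the same way. A locus value is thus the sum over promoter and distal peaks. Gene lists were fixed before the data were examined: inflammatory cytokines and NF-kB targets, interferon-stimulated genes, negative regulators of LPS signalling, immediate early and AP-1 genes, homeostatic microglia genes, disease-associated or primed microglia genes, antigen presentation, trained immunity metabolism, proliferation, and markers of border and bone-marrow-derived macrophages, monocytes, neutrophils, lymphocytes, oligodendrocytes, astrocytes, neurons, and endothelial and mural cells. They were tested with camera from limma 3.58.1 on log2 CPM of locus sums with a prior count of 2, with a preset correlation of 0.01 and again with an estimated correlation, and adjusted over the lists within a comparison. Pairs of lists shared at most 1 gene. Members were counted as called over all loci tested and also adjusted over the list alone.

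The genes named in the text follow a rule fixed before the data were examined. For each comparison it takes the 10 called peaks with the smallest p in each direction, at most 1 per gene, whose libraries did not overlap between the groups, named by the nearest start site within 50 kb and by position otherwise. It adds up to 4 members of each list, namely the 2 with the smallest p in each direction, and a fixed set of genes (Tnf, Il1b, Ccl2, Ccl3, Ccl4, Nfkbia, Acod1, Socs3, P2ry12, Tmem119, Sall1, Apoe, Ifit3 and Irf7), of which Apoe had no tested peak. Outside this rule are the peaks named for the difference in LPS response, the Zbtb16 peaks, which lie beyond 50 kb of a start site and are named by the intron they lie in, and the glucocorticoid target loci.

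Depth ranged from 927840 to 2772688 rounded counts in peaks per library. The chi-square per degree of freedom between replicates was 0.994 to 1.2 outside the PL pair and 2.04 for the PL pair. A value of 1 is counting noise alone only if each deposited unit is 1 independent event. The counts come in fractional steps from a tool that is not given, so the value for counting noise alone is not known. Under that assumption the LBL pair differed by no more than counting noise (p = 0.738 by the chi-square test over 25913 peaks). Whether the assumption holds was not tested. The 2 libraries were kept as 2, and averaging them into 1 sample was run as an alternative. Replicate numbers are shared across groups without a stated pairing, so replicate was a block in an alternative and not in the fit reported. The intervals given for shares of peaks are exact Clopper-Pearson intervals at the 95% level and treat peaks as independent.

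The test was checked on simulated data, with 200 changed peaks per comparison placed in negative binomial counts drawn with the observed mean share and dispersion of each peak and the observed library totals. It recovered 8.96% to 20.9% of the peaks changed by a factor of 1.5 and 37.3% to 62.7% of those changed by a factor of 2. At a factor of 4 it recovered 81.8% to 97%, and no sign was wrong. Each peak had the same dispersion in all groups, so the wider spread of the PL pair was not simulated. Between 1.1% and 9.48% of the calls were false.

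Alternatives set before the data were examined were DESeq2 1.42.0 size factors, scaling by library size, cyclic loess offsets, the DESeq2 Wald test, limma-trend, no filter and a stricter filter on low counts, a fit to the compared groups alone, the replicate block, an additive model with the sorter, a minimum absolute log2 fold change of 1, each library left out in turn, narrower windows of 1 kb and 10 kb for gene loci, a wider definition of promoters, and the estimated correlation. Alternatives chosen after the data were seen were unrounded counts, counts doubled to read ends, isolation day as a term, libraries thinned to equal totals, X and Y chromosome peaks left out, and the LBL libraries averaged. Where leaving a library out left 1 library in a group, that library was assumed to vary like those of the other groups. A motif analysis, which needs the genome sequence, was planned and is not analysed here.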

Results

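Microglia, the resident macrophages of the brain, were sorted from mice that received a first intraperitoneal injection at 10 weeks of age, a course of BLZ945 or vehicle from 1 week later, and another injection 5 weeks after the first. BLZ945 blocks CSF1R, the receptor on which microglia depend for survival, and was given at 169 mg/kg per day for 5 days, so that microglia are lost and the brain is then repopulated. The injections held LPS, a bacterial cell wall component that activates Toll-like receptor 4, at 1 mg/kg, or PBS. Cells were collected 3 hours after the last injection at an age of 15 weeks. The groups are named by the order of the treatments, with P for PBS, L for LPS and B for BLZ945. PP and PBP received PBS only, PL and PBL received LPS for the first time before collection, and LL and LBL received LPS at both times. PBL had 3 libraries and each other group had 2.

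The libraries held 927840 and 990266 rounded counts in peaks for PP, 1653191 and 1316675 for PBP, and 1692751 and 1861139 for PL. PBL held 1444372, 2199759 and 2772688, LL 2013926 and 2494980, and LBL 1547545 and 1985467. The 4 PBS libraries lay apart from the 9 LPS libraries along the first principal component, which carried 27.8% of the variance. The PL pair was the widest, at 10.7 for PL 1_2 and 41.4 for PL 3_4 on that component. PL 3_4 had 53.2% of its counts in promoter peaks, while the other 12 libraries had 55.5% to 60.1%. PP, PBP and PL were sorted on an Astrios instrument and PBL, LL and LBL on an XDP instrument. Each group except PL was isolated on a single day. PL 1_2 shared its day with PBP and PL 3_4 with PP, while PBL, LL and LBL each had a day of their own, so for these groups day and group cannot be told apart. Among the comparisons PL vs PP, PBP vs PP, LBL vs PBL and LBL vs LL stayed within 1 sorter.

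**Figure D1:**
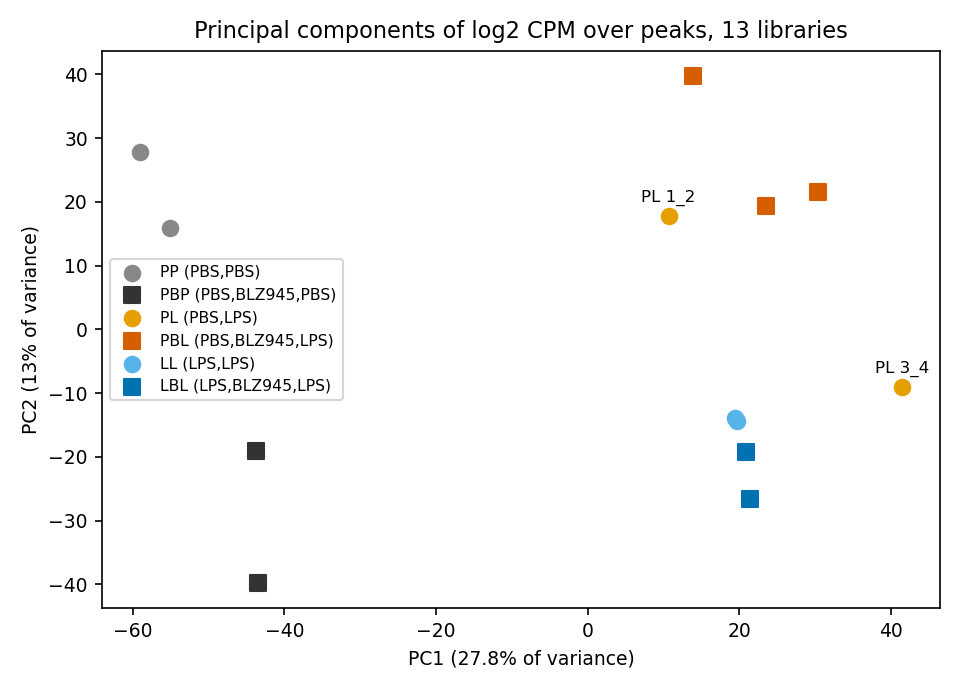
Principal components of log2 CPM over the peaks, with each point a library and the axes giving PC1 (27.8% of the variance) and PC2 (13% of the variance). The PP and PBP libraries lie at the left and the LPS libraries at the right, with PL 1_2 at 10.7 and PL 3_4 at 41.4 on PC1.

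The comparison of PL with PP asked how a first LPS challenge changes accessibility in microglia that were never depleted. The promoter of Map3k8, which encodes a kinase that relays Toll-like receptor signals to ERK, opened most clearly, at chromosome 18, 4336162 to 4336932. Its level was 113 ± 7.68 CPM (SD, n = 2) in PL and 20.5 ± 0.761 CPM (SD, n = 2) in PP, a 5.53-fold rise (log2 2.47 ± 0.203 SE, adjusted p = 8.71e-20). Peaks near Rbpj, the nuclear effector of Notch signalling, and Kcnn4, a calcium-activated potassium channel, rose 4.26-fold and 4.03-fold. Accessibility fell at the promoter of Mertk, a receptor for the uptake of dying cells, by 1.14 ± 0.161 (SE) on the log2 scale (chromosome 2, 128698133 to 128699398, adjusted p = 6.27e-08). It also fell at an intergenic peak 22969 bp from the start site of Siglech, a microglial surface lectin, by 1.71 ± 0.264 (chromosome 7, 55744255 to 55745209, adjusted p = 7.83e-07).

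In all, 2799 of 37516 peaks were called, 1791 higher and 1008 lower in PL, and 1457 gene loci, 898 higher and 559 lower. Further peaks among the 10 most significant rises lay in introns of Ildr1 (4.68-fold) and Aig1 (3.88-fold), 38153 bp from Slc44a3 (3.68-fold), and on chromosome 16 at 93246704 (6.19-fold), chromosome 13 at 107607161 (4.9-fold), chromosome 2 at 73037288 (3.55-fold) and chromosome 19 at 21031643 (2.73-fold), the last 4 beyond 50 kb of a start site. Among the 10 most significant falls were peaks at Mid1 and Pak3 on the X chromosome (2.73-fold and 2.22-fold lower), at Cldn34d (2.33-fold lower) and at the promoter of 4931408C20Rik (2.42-fold lower). Peaks on the Y chromosome at 259037 and near G530011O06Rik were 3.17-fold and 2.24-fold lower, and chromosome 4 peaks at 147342983 and 3082993 were 3.1-fold and 2.06-fold lower. At these peaks PP stood apart from PBP too, which received no LPS: means in PP, PBP and PL were 162, 62.5 and 59.6 CPM at Mid1, 190, 101 and 85.9 at Pak3, 99.2, 39.7 and 31.2 at the Y chromosome peak, and 148, 73.8 and 61.5 at 4931408C20Rik. At Mertk they were 122, 98.9 and 56 CPM and at Siglech 47.1, 42.4 and 14.5. All 20 of these peaks were called with each library left out, and by DESeq2 and limma-trend. Higher calls were poor in promoter peaks, at 17.4% (95% interval 15.6 to 19.2) against 36.8% of all tested peaks, and lower calls were rich in them, at 63.5% (60.4 to 66.5; Fisher's exact test, adjusted p = 2.87e-75 and 3.18e-67). Without PL 3_4, the library with the lowest promoter share, 33.9% of the 180 lower peaks were promoter peaks.

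Of 31 measured loci of inflammatory cytokines and NF-kB targets, 12 rose in PL, none fell and 19 were not called (15 higher adjusted over the list alone). They included Birc3, an inhibitor of apoptosis (2-fold), the receptor gene Tlr2 (1.5-fold), the cytokine gene Tnf (log2 0.596 ± 0.187, adjusted p = 0.027) and Nfkbia, the inhibitor of NF-kB (log2 0.337 ± 0.109, adjusted p = 0.0322). Of 32 interferon-stimulated loci 8 rose (10 adjusted over the list alone), with the chemokine genes Cxcl10 and Cxcl11 at 2.25-fold and 2.17-fold. Of 25 negative regulators of LPS signalling 6 rose (8 adjusted over the list alone), among them the interleukin 4 receptor Il4ra (1.6-fold), Sbno2 (1.49-fold) and Socs3, a feedback inhibitor of cytokine receptors (log2 0.372 ± 0.0989, adjusted p = 0.00756). Of 27 disease-associated or primed microglia loci 6 rose (8 adjusted over the list alone), including Spp1, which encodes osteopontin (2.14-fold), and the cathepsin Ctsz (1.47-fold). These 4 lists were called higher by camera, with median log2 fold changes of 0.337, 0.195, 0.22 and 0.185 and adjusted p of 4.31e-05, 0.00331, 0.0141 and 0.0141. With an estimated correlation none of the 4 passed (adjusted p = 0.175, 0.175, 0.175 and 0.442). Without PP 3_4 the last 3 lists were not called (0.0719, 0.0719 and 0.132), nor were the negative regulators without PL 1_2 (0.0596) or the disease-associated loci without PL 3_4 (0.257). These 2 lists were also not called over peaks within 1 kb (0.498 each).

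Homeostatic microglia loci went both ways in PL, with 2 higher, 6 lower and 21 not called of 29 (6 and 7 adjusted over the list alone), and the list was not called (adjusted p = 0.237), while without PL 3_4 it was called lower (median -0.126, adjusted p = 0.00969). Mertk and Siglech fell by 0.781 ± 0.112 and 0.847 ± 0.152 on the log2 scale, Sall1, a transcription factor of microglial identity, fell by 0.632 ± 0.14, and Mef2c and P2ry13 rose 1.27-fold and 1.35-fold. Immediate early and AP-1 loci had 4 higher and 1 lower of 23 (adjusted p = 0.218), with Ier3 (1.71-fold) and Fosl2 (log2 0.467 ± 0.11) higher and Jund lower (1.4-fold). Over peaks within 1 kb of the start site alone, the Fosl2 and Siglech loci were at -0.00875 and 0.0447. Il1b, Ccl2, Ccl3, Ccl4, Acod1, P2ry12, Tmem119, Ifit3 and Irf7 were not called, with log2 fold changes between -0.352 and 0.273. The remaining lists were not called: antigen presentation (adjusted p = 0.931), trained immunity metabolism (0.818), proliferation (0.861), border and bone-marrow-derived macrophage markers (0.266), and markers of monocytes (0.516), neutrophils (0.861), lymphocytes (0.861), oligodendrocytes (0.861), astrocytes (0.544), neurons (0.127, and 0.0141 without PL 3_4), and endothelial and mural cells (0.818). The median and mean of the trained immunity, proliferation and neutrophil lists differed in sign, and camera gave the neutrophil list (mean 0.0603) and the lymphocyte list (median 0.229, mean 0.015) a downward direction. Single loci were called among them, with the glucose transporter Slc2a1 (1.55-fold), the costimulatory receptor Cd86 (1.56-fold), F13a1 (2.61-fold) and Trem1 (2.96-fold) higher and the MHC class I gene H2-K1 1.48-fold lower.

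The number of calls depended on single libraries. It was 681 without PL 3_4, 5109 without PL 1_2, 841 without PP 1_2 and 986 without PP 3_4, and 12 of 34 named loci kept their call without each library in turn (Birc3, Cxcl10, Cxcl11, Il4ra, Sbno2, Ier3, Mertk, Siglech, Cd86, Slc2a1, Dab2 and F13a1). DESeq2 called 808 peaks, limma-trend 4288 and a model with isolation day as a term 5090. In that model the day effect is the difference between PL 3_4 and PL 1_2. Its calls thus set PL 3_4 against PP, and they cannot tell a day effect from a trait of that library.

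**Figure D2:**
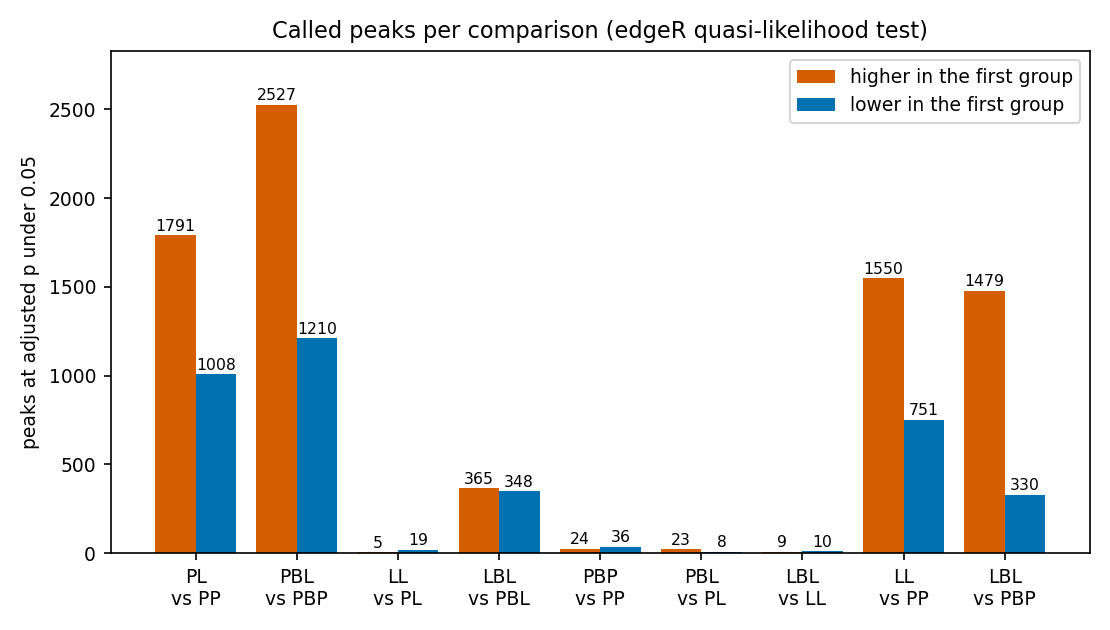
Number of peaks called at an adjusted p under 0.05 in each comparison (vertical axis), with orange bars for peaks higher and blue bars for peaks lower in the first-named group. The comparisons of LPS with PBS had between 1809 and 3737 calls, LBL vs PBL had 713, and LL vs PL and the repopulation comparisons had between 19 and 60.

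The comparison of PBL with PBP asked the same question in repopulated microglia. The Map3k8 promoter again rose most clearly, 4.61-fold (log2 2.21 ± 0.162 SE, adjusted p = 9.15e-24), from 23.7 ± 3.62 CPM (SD, n = 2) in PBP to 110 ± 7.91 CPM (SD, n = 3) in PBL. Peaks near Bcl3, a nuclear cofactor of NF-kB, and at the promoter of Vmp1, an autophagy protein, rose 3.1-fold and 2.98-fold. A peak 24968 bp from the start site of Gpr34, a lysophosphatidylserine receptor of microglia, fell by 3.46 ± 0.388 (SE) on the log2 scale (chromosome X, 13606822 to 13607121, adjusted p = 2.09e-12), from 20.5 ± 8.31 to 1.95 ± 1.08 CPM. The same Siglech peak as above fell by 1.87 ± 0.227 (adjusted p = 5.59e-11).

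In all, 3737 peaks were called, 2527 higher and 1210 lower in PBL, and 1026 gene loci, 707 higher and 319 lower. Further named rises were at peaks near Noct (7.37-fold), Tmem131l (6.02-fold), Aig1 (5.72-fold), Popdc2 (4.61-fold) and Tbc1d14 (4.52-fold), at the chromosome 16 peak at 93246704 (8.19-fold) and at chromosome 9, 70284585 (4.12-fold). Further named falls were near Atf7ip (4.84-fold lower), Csmd3 (3.81-fold lower), D7Ertd443e (3.62-fold lower), Mthfs (3.16-fold lower), Pepd (2.57-fold lower) and Vsir, which encodes the immune checkpoint VISTA (2.39-fold lower). Peaks on chromosome 3 at 103401066 and chromosome 2 at 173335632 were 2.75-fold and 2.63-fold lower. All 20 named peaks were called with each library left out, and by DESeq2 and limma-trend. Promoter peaks made up 16.4% of the higher and 17% of the lower calls (95% intervals 15 to 17.9 and 14.9 to 19.3; Fisher's exact test, adjusted p = 3.33e-119 and 1.32e-52).

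Of the 31 inflammatory loci 13 rose in PBL, none fell and 18 were not called (19 higher adjusted over the list alone), with a median of 0.367 (adjusted p = 2.46e-12, and 0.0219 with an estimated correlation). Tnf rose 2.27-fold (log2 1.18 ± 0.172, adjusted p = 4.06e-07), Birc3 1.82-fold, and Nfkbia by 0.308 ± 0.0894 on the log2 scale. Of 25 negative regulators 8 rose (9 adjusted over the list alone), with Dusp2, a MAP kinase phosphatase, at 1.75-fold and Socs3 at 1.52-fold; the list was called (median 0.184, adjusted p = 9.53e-06, and 0.0114 with an estimated correlation). Of 29 homeostatic loci 11 fell, 1 rose and 17 were not called (15 lower and 1 higher adjusted over the list alone), with a median of -0.215 (adjusted p = 1.41e-11, and 0.0114 with an estimated correlation). Gpr34 fell by 1.55 ± 0.189, Siglech by 1.16 ± 0.13, Tmem119, a microglial membrane protein, by 0.583 ± 0.132 and Sall1 by 0.459 ± 0.11 on the log2 scale, and Gpr84, a fatty acid receptor induced by inflammation, rose 1.36-fold.

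Immediate early and AP-1 loci (5 higher and 1 lower of 23) and disease-associated loci (7 higher and 1 lower of 27, 8 and 1 adjusted over the list alone) were called higher with small medians of 0.0676 and 0.0874. Both had adjusted p = 0.0152, and 0.297 with an estimated correlation, and neither was called without PBL 3_4 (0.0981 and 0.0723). The immediate early call was also lost without PBP 3_4 (0.112), and the disease-associated call within 1 kb or 10 kb (0.239 and 0.0539). Ier3 and Fosl2 rose 1.93-fold and 1.54-fold, Jun was 1.2-fold lower, Cst7, which encodes cystatin F, rose 2.57-fold, and Cd300lf rose 1.64-fold. Of 32 interferon-stimulated loci 4 rose (5 adjusted over the list alone), including Cxcl10 (1.82-fold) and Cxcl11 (1.62-fold), and the list lay near the threshold (adjusted p = 0.0631). It was called over peaks within 1 kb (0.00179) and 10 kb (0.0185) and without PBP 3_4 (0.0284) or PBL 1_2 (0.0197), with medians of 0.0963 to 0.195 over left-out libraries. The other 11 lists had adjusted p between 0.106 and 0.652, and border macrophage markers 0.0284 without PBP 3_4, with F13a1 (2.04-fold), Trem1 (3.83-fold), Cd36 (1.76-fold), Cldn5 (1.82-fold) and Slc2a1 (1.6-fold) called higher among their loci. The proliferation list (median -0.0261, mean 0.00248) and the neuron list (0.0876 and -0.0348) differed in sign between median and mean, and the oligodendrocyte list (median 0.0614) was given a downward direction by the test. Of the fixed genes, Il1b, Ccl2, Ccl3, Ccl4, Acod1, P2ry12, Ifit3 and Irf7 were not called.

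The number of calls was 1732 without PBP 1_2 and 1776 without PBP 3_4, and 2813 to 3453 without each PBL library. DESeq2 called 1213 peaks and thinning to equal totals left 1837, and of 28 named loci 10 lost their call without some library (Cxcl10, Cxcl11, Jun, Atp6v0d2, Pfkfb3, Opalin, Cldn5, Nfkbia, Tmem119 and Sall1).

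The LPS responses with and without depletion share no library, so their overlap was counted directly. Of the 2799 peaks called in PL vs PP, 2380 (85%, 95% interval 83.7 to 86.3) had the same sign in PBL vs PBP. The higher peaks did so in 91.5%, with a median of 1.07 in PL vs PP and 0.675 in PBL vs PBP. The lower peaks did so in 73.6%, with medians of -0.849 and -0.168. Peaks called higher in both numbered 950, against 121 expected from the margins, and those called lower in both 150, against 32.5. Across all tested peaks, which are not independent replicates, the fold changes correlated with Pearson's r of 0.441 and Spearman's rho of 0.364. The share of all peaks called in PL vs PP with the same sign in PBL vs PBP was 94.1% without PL 3_4 and 78.2% without PL 1_2. A direct test of the difference between the responses called 28 peaks, 22 higher and 6 lower in the repopulated arm, and 17 loci. Of the 28 peaks, 17 were lower in PL vs PP and not called in PBL vs PBP, among them a Mid1 peak at 170019497 (-1.54 ± 0.238 and 0.262 ± 0.251, difference 1.8 ± 0.343, adjusted p = 0.0121) and the promoters of Srsf2 (-0.782 ± 0.128 and 0.0706 ± 0.115, difference 0.852 ± 0.172, adjusted p = 0.0182) and Inpp5k (-0.89 ± 0.167 and 0.188 ± 0.144, difference 1.08 ± 0.22, adjusted p = 0.0182). At Srsf2 the difference lies in the PBS groups, with means of 207 and 130 CPM in PP and PBP and 121 and 137 CPM in PL and PBL. PBP vs PP was called there without LPS (-0.668 ± 0.13, adjusted p = 0.00212). The 2 peaks higher in PBL vs PBP and not called in PL vs PP were at Ehd1 and Kdm6b. The promoter of Ehd1, an endocytic recycling protein, rose by 1.11 ± 0.169 in PBL vs PBP and was at -0.0544 ± 0.2 in PL vs PP (difference 1.16 ± 0.267, adjusted p = 0.0448). An intronic peak of Kdm6b, a histone H3K27 demethylase, was at 0.68 ± 0.14 and -0.233 ± 0.161 (difference 0.913 ± 0.214, adjusted p = 0.0469). The count was 1037 without PL 1_2, 0 without PL 3_4, 0 without PP 1_2, 15 without PP 3_4, 2 without PBP 3_4 and 0 without PBL 1_2. PBL is the one group of these 4 sorted on the XDP instrument and has its own day, so sorter and day cannot be separated from this difference.

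The comparison of LL with PL asked whether an LPS challenge 5 weeks earlier altered the accessibility reached after a later one, without depletion. Few peaks differed. A peak 13988 bp from Crlf3, a cytokine receptor-like gene, fell by 2.2 ± 0.393 (SE) on the log2 scale (chromosome 11, 80043416 to 80043911, adjusted p = 0.0012), from 14.6 ± 0.484 CPM in PL to 3.06 ± 0.796 CPM in LL (SD, n = 2 each). The promoters of Tmbim1 and of Il4i1, an amino acid oxidase of activated myeloid cells, were 2.44-fold and 2.58-fold lower (adjusted p = 0.000531 and 0.0227). A peak in an intron of Zbtb16 on chromosome 9, 48744940 to 48745377, was 2.21-fold higher (adjusted p = 0.0147), and a peak 23944 bp from Il12a, a subunit of interleukin 12, was 2.49-fold higher (adjusted p = 0.0369).

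In all, 24 peaks were called, 5 higher and 19 lower in LL, with 2933 at an unadjusted p under 0.05, and 6 loci, 2 higher and 4 lower. The other named falls were near Specc1l (3.18-fold), 3425401B19Rik (2.13-fold) and Tspan18 (4.22-fold) and at peaks on chromosomes 16, 8, 12 and 1 at 84621258, 9008081, 86819090 and 77280490 (2.2-fold, 2.34-fold, 2.09-fold and 2.61-fold). The other named rises were at the promoters of Aatk (1.68-fold) and Sh3bp1 (2.85-fold) and at chromosome 14, 62001339 (2.27-fold). Homeostatic microglia loci shifted upward as a list, with a median of 0.124 (adjusted p = 1e-09, and 0.0349 with an estimated correlation). Of its 29 loci Mertk was called over all loci (1.39-fold higher, adjusted p = 0.0444), and 10 were called higher adjusted over the list alone. Interferon-stimulated loci shifted downward with a median of -0.155 (adjusted p = 0.00742, and 0.28 with an estimated correlation), with none of 32 called and 2 lower adjusted over the list alone. The call was lost without PL 3_4 or LL 3_4 (adjusted p = 0.175 and 0.185). Inflammatory loci had a median of -0.075 (adjusted p = 0.0603), with none of 31 called and 1 lower adjusted over the list alone. Their median ran from -0.137 to 0.0346 over left-out libraries, and the list was called lower without PL 1_2 (adjusted p = 0.00223) or LL 1_2 (0.0431), within 1 kb (0.0021) and 10 kb (0.0458), with library sizes (0.0437) and with the replicate block (0.0444). The other 14 lists had adjusted p between 0.149 and 0.878. Among these, the disease-associated list (median 0.0507, mean -0.0203, and called higher without PL 3_4, adjusted p = 0.0167) and the monocyte list (-0.0389 and 0.0368) differed in sign, and the negative regulators (median -0.0144) were given an upward direction by the test. None of the fixed genes was called, with Tnf at -0.195 ± 0.147 and Socs3 at 0.236 ± 0.0856.

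These calls were not stable: 304 peaks were called without PL 1_2, 6 without PL 3_4, 5 without LL 1_2 and 8 without LL 3_4, none of the 15 named peaks was called in each of these fits, and DESeq2 called 0 and limma-trend 4. PL and LL also differ in sorter and day. An additive model with the sorter as a term called 1120 peaks for a priming effect assumed equal in both arms. There the PL level cancels out, and the estimate is a fitted LBL level set against PBL. The 1120 calls are thus no sorter-adjusted result for LL vs PL.

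The comparison of LBL with PBL asked whether the earlier LPS challenge left a mark after the microglia present at that time had been depleted and replaced, within 1 sorter. The promoter of Tnfaip3, which encodes the NF-kB inhibitor A20, fell by 1.32 ± 0.211 (SE) on the log2 scale (chromosome 10, 19009170 to 19009739, adjusted p = 1.7e-05), from 43.9 ± 10.2 CPM in PBL (SD, n = 3) to 17.8 ± 4.97 CPM in LBL (SD, n = 2). The same peak had a mean of 15.6 CPM in PBP (n = 2). The Crlf3 peak fell by 2.18 ± 0.325 (adjusted p = 3.27e-06), and the promoter of Slc11a1, a phagosomal metal transporter, by 1.51 ± 0.236 (adjusted p = 1.12e-05). The promoters of Vps35l, part of an endosomal recycling complex, and Crybb1, a crystallin gene expressed in microglia, rose 2.99-fold and 2.64-fold (adjusted p = 1.43e-05 and 7.53e-05).

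In all, 713 peaks were called, 365 higher and 348 lower in LBL, and 166 gene loci, 97 higher and 69 lower. The other named falls were near Abhd16b (4.23-fold), Rab11fip4os1 (5.01-fold), the complement protease gene C1s2 (3.97-fold), Zmynd15 (3.6-fold) and 3425401B19Rik (2.36-fold), and on chromosome 12 at 86819090 and 25213693 (3.04-fold and 2.16-fold). The other named rises were at Mycbp2 (2.59-fold), Mthfs (2.41-fold), the promoter of Abhd12 (1.68-fold), and peaks on chromosome 10 at 100159736, chromosome 8 at 89286154, chromosome 1 at 62608705 and chromosome 2 at 160156536 and 117961976 (1.9-fold, 3.87-fold, 2.84-fold, 3.7-fold and 1.79-fold). Promoter peaks made up 8.49% of the higher and 25.3% of the lower calls (95% intervals 5.84 to 11.8 and 20.8 to 30.2; Fisher's exact test, adjusted p = 2.41e-35 and 1.1e-05).

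Of 31 inflammatory loci 4 fell in LBL, none rose and 27 were not called (10 lower adjusted over the list alone), with a median of -0.221 (adjusted p = 1.19e-08, and 0.0591 with an estimated correlation). Cd40, a costimulatory receptor, was 3.67-fold lower and Birc3 1.49-fold lower; Tnf was at -0.505 ± 0.148 (adjusted p = 0.0683) and none of the fixed genes was called. Of 29 homeostatic loci 5 rose and none fell (13 higher adjusted over the list alone), with a median of 0.198 (adjusted p = 1.77e-13, and 0.0135 with an estimated correlation); Mertk rose 1.39-fold. Of 20 antigen presentation loci 2 fell, Cd40 and H2-K1 (log2 -0.462 ± 0.129), with 3 lower adjusted over the list alone and a median of -0.154 (adjusted p = 0.00114, and 0.0455 with an estimated correlation). Of 23 immediate early and AP-1 loci 3 fell (5 adjusted over the list alone), among them Maff (2.02-fold lower) and Fosb (1.37-fold lower), with a median of -0.0883 (adjusted p = 0.000516, and 0.114 with an estimated correlation). Border and bone-marrow-derived macrophage markers had a median of 0.186 (adjusted p = 0.0361, and 0.321 with an estimated correlation), with Runx3 1.42-fold lower as the single call and 4 higher and 1 lower adjusted over the list alone. The call was lost without PBL 4_5 or LBL 3_4 (adjusted p = 0.0502 and 0.187), within 10 kb (0.0848) and with the replicate block (0.0508). The other 12 lists had adjusted p between 0.0853 and 0.854, and median and mean differed in sign for the disease-associated (0.0159 and -0.00521), neutrophil (-0.00531 and 0.018) and lymphocyte lists (0.0478 and -0.0493). Of these 12, interferon-stimulated loci were called lower within 1 kb (0.0206) and without PBL 1_2 (0.0491), and neuron markers without LBL 1_2 (0.0243). Beside these, the MAP kinase phosphatase genes Dusp2 and Dusp1 (1.82-fold and 1.24-fold lower), the growth factor gene Csf1 (1.37-fold lower) and the endothelial gene Cldn5 (2.19-fold lower) were called among their loci.

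The number of calls fell to 88 without LBL 1_2 and 94 without LBL 3_4, to 396 without PBL 3_4 and 334 without PBL 4_5, and to 23 with the LBL libraries averaged into 1 sample, and without LBL 1_2 or LBL 3_4 none of the homeostatic loci was called over all loci while the list kept its call. DESeq2 called 17 peaks and limma-trend 263, and of the named items 16 of 20 peaks and, among 12 loci, Dusp2 and Maff kept their call without each library.

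**Figure D3:**
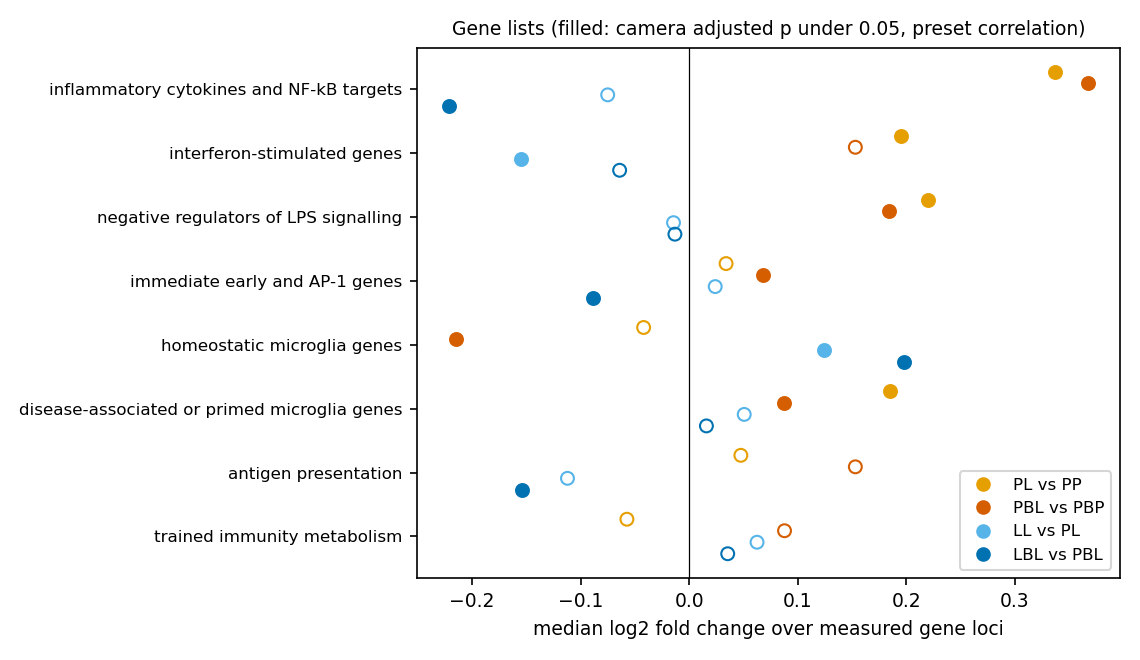
Median log2 fold change over the measured loci of 8 gene lists (horizontal axis) in 4 comparisons, with filled points for lists called by camera at the preset correlation. Homeostatic loci lie at -0.215 in PBL vs PBP and at 0.124 and 0.198 in LL vs PL and LBL vs PBL, and inflammatory loci at 0.367 in PBL vs PBP and -0.221 in LBL vs PBL.

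The effect of the earlier challenge was then compared between the arms, which again share no library. Of the 713 peaks called in LBL vs PBL, 592 had the same sign in LL vs PL (83%, 95% interval 80.1 to 85.7), and of the 348 lower ones 306 did (87.9%), with a median of -0.435 there. Conversely, 22 of the 24 peaks called in LL vs PL had the same sign in LBL vs PBL (91.7%, 73 to 99). Peaks lower in both numbered 13, against 0.176 expected from the margins, among them those near Crlf3 and 3425401B19Rik and the chromosome 12 peak at 86819090. Across all tested peaks Pearson's r was 0.239 and Spearman's rho 0.2. The shared share was 72.6% without PL 1_2 and 77.8% without PL 3_4. A direct test of the difference between the arms called 0 peaks with edgeR, 0 with DESeq2 and 0 with limma-trend, with 2596 at an unadjusted p under 0.05 (6.92% of peaks), and 71 without PL 1_2 and 1 without PL 3_4.

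**Figure D4:**
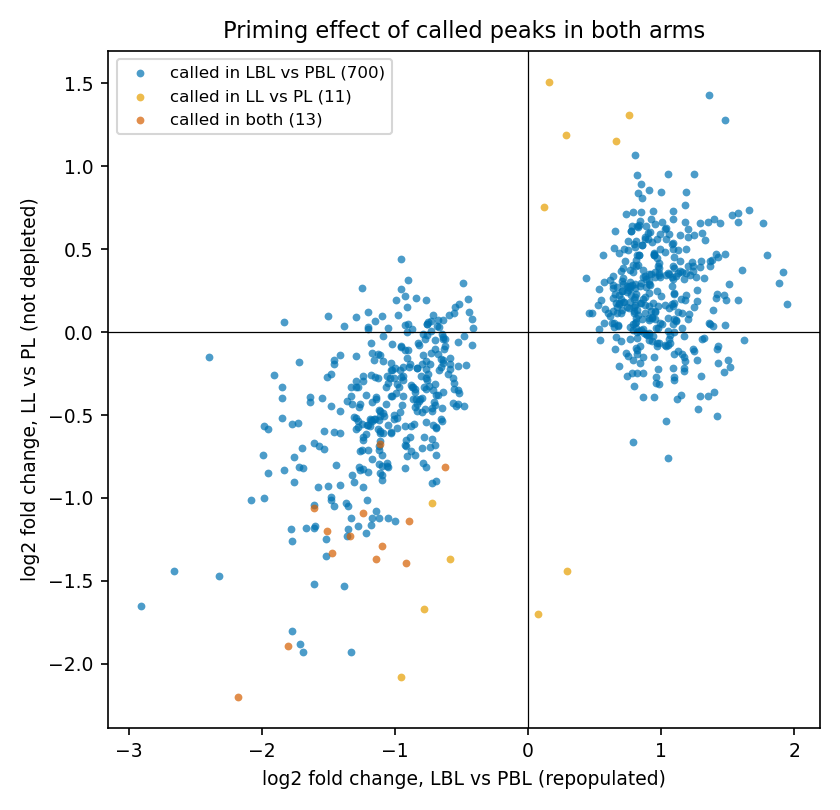
Log2 fold change of LBL vs PBL (horizontal axis) and LL vs PL (vertical axis) for peaks called in either, with each point a peak. The 13 peaks called in both are all lower in the primed group of both arms.

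The peaks that LPS opened were also examined in primed mice, with the peaks chosen in the arm that was not tested. The 2527 peaks higher in PBL vs PBP had a median log2 fold change of -0.109 in LL vs PL, where 13 were called lower and 1 higher (camera p = 1.96e-06, and 0.0944 with an estimated correlation). The 1210 peaks lower in PBL vs PBP had a median of 0.148 there (p = 4.92e-07, and 0.00335 with an estimated correlation). The first median was -0.00431 without PL 3_4 and -0.203 without PL 1_2. The 1791 peaks higher in PL vs PP had a median of -0.0482 in LBL vs PBL (camera p = 0.0612, and 0.632 with an estimated correlation), and of -0.00143 without PBL 3_4. The 1008 peaks lower in PL vs PP had a median of -0.0594 there (camera p = 0.0576, and 0.687 with an estimated correlation), opposite in sign to the lowered set of the other arm. Of the 348 peaks lower in LBL vs PBL, 78 were called higher in PL vs PP, while 4.77% of all tested peaks were (Fisher's exact test, p = 8.75e-31). Of the 365 peaks higher in LBL vs PBL, 8 were called lower in PL vs PP and 22 higher, with a median of 0.0236 (Fisher's exact test for lower calls, p = 0.743).

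Repopulation itself was examined at each state of challenge. An intronic peak 4646 bp from a start site of Cd36, a scavenger and lipid receptor (chromosome 5, 17854438 to 17854984), was higher in repopulated microglia in all 3 comparisons. It rose 3.14-fold in PBP vs PP (log2 1.65 ± 0.341 SE, adjusted p = 0.0052), 1.83-fold in PBL vs PL (0.874 ± 0.18, adjusted p = 0.0205) and 2.79-fold in LBL vs LL (1.48 ± 0.215, adjusted p = 4.92e-06). Group means were 9.8 ± 3.99, 28.8 ± 10.5 and 16.8 ± 1.23 CPM (SD, n = 2 each) in PP, PL and LL, and 30.6 ± 1.64 (n = 2), 53.3 ± 4.72 (n = 3) and 47.5 ± 1.79 CPM (n = 2) in PBP, PBL and LBL. Without some library the peak lost its call in PBP vs PP and in PBL vs PL, and in LBL vs LL it kept it. The Cd36 locus kept its call without each library in PBL vs PL (1.83-fold) and LBL vs LL (2.87-fold).

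**Figure D5:**
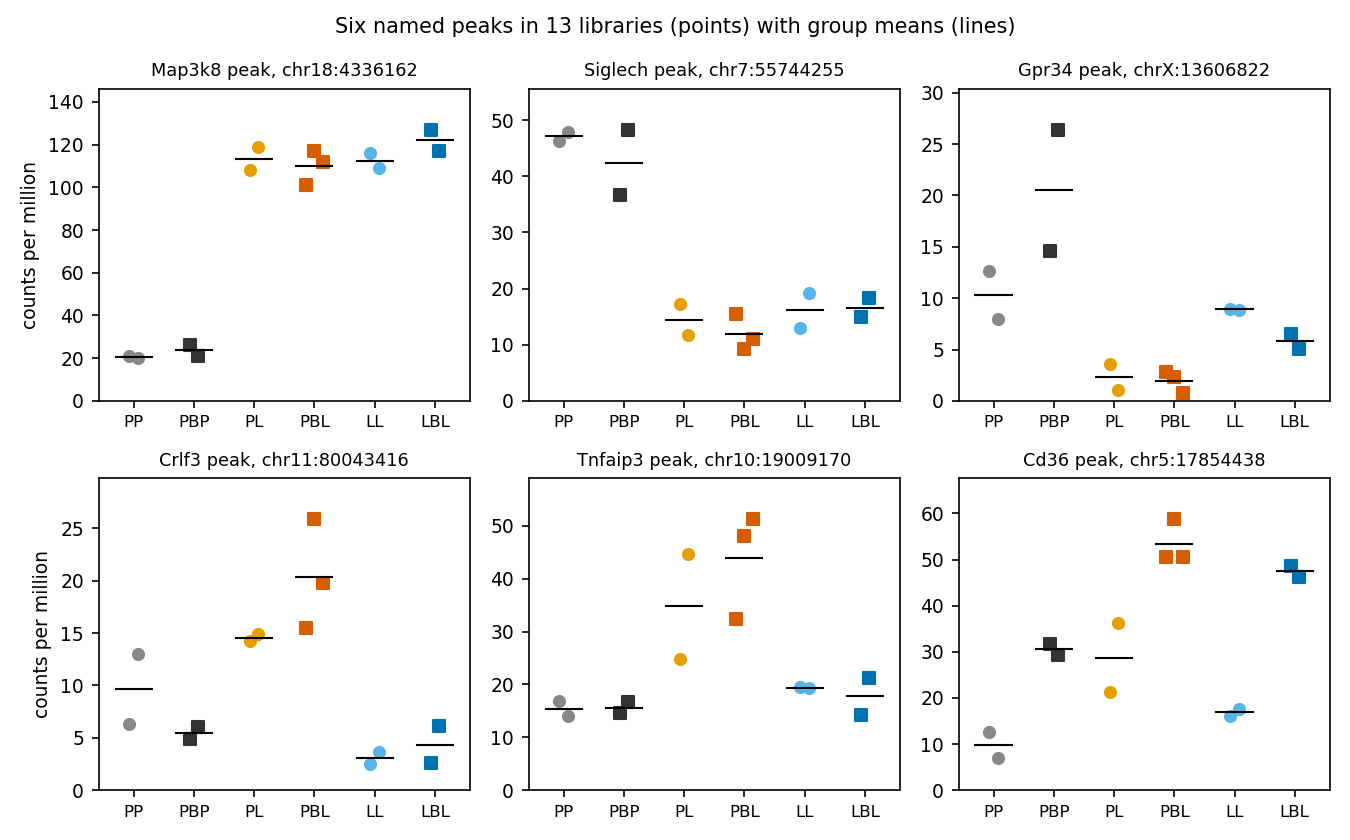
CPM of 6 named peaks (vertical axes) in the 13 libraries, with points for libraries and lines for group means. The Map3k8 peak lies at a mean of 20.5 in PP and 113 in PL, the Tnfaip3 peak at 43.9 in PBL and 17.8 in LBL, and the Cd36 peak at 16.8 in LL and 47.5 in LBL.

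In mice without LPS, PBP vs PP, 60 peaks were called, 24 higher and 36 lower in PBP, and 16 loci, 4 higher and 12 lower. Promoters of Gsk3b, a signalling kinase, Ppp2r1a and Ppp2r5a, subunits of phosphatase 2A, and Bcl10, an NF-kB adaptor, rose 1.54-fold, 1.58-fold, 1.49-fold and 1.5-fold. Promoters of Ccng2, Dcaf15 and Eny2 rose 1.73-fold, 1.73-fold and 1.52-fold, and peaks near Cdkn2aipnl and at chromosome 10, 125748837 rose 2.23-fold and 1.93-fold. Peaks at Mid1, Pak3, G530011O06Rik, 4931408C20Rik, Cldn34d and Gm21190, on the Y chromosome at 259037, and on chromosomes 6 and 4 at 3182420 and 147123379 were 1.87-fold to 7.91-fold lower, and the promoter of the splicing factor Srsf2 was 1.59-fold lower. Homeostatic loci had a median of 0.186 (adjusted p = 0.000388, and 0.303 with an estimated correlation), with none of 29 called and 2 higher adjusted over the list alone, and the other 16 lists had adjusted p between 0.0524 and 0.895, with median and mean of opposite sign for border macrophage (-0.00112 and 0.015) and monocyte markers (-0.0448 and 0.0493). Over peaks within 1 kb the homeostatic list was not called (0.0856). Interferon-stimulated loci were called higher without PP 1_2 (0.0067) or PBP 1_2 (0.0436), neuron markers lower without PBP 3_4 (0.00969), and both with library sizes (0.0472 each). The split depended on the scaling, with 40% of the calls higher here, 28.6% with library sizes and 11.4% with cyclic loess offsets. The model with isolation day takes its day effect from the PL pair alone, so its count for PBP vs PP is PP shifted by the difference between those pools. The count was 10 without PP 1_2, 29 without PP 3_4, 19 without PBP 1_2, 20 without PBP 3_4, 34 without X and Y chromosome peaks, 9 with DESeq2, 421 with limma-trend and 815 with isolation day, which differs between PBP and PP, as a term.

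After a first LPS challenge, PBL vs PL, 31 peaks were called, 23 higher and 8 lower in PBL, and 47 loci, 23 higher and 24 lower. Beside Cd36, peaks at Sh3pxd2b (2.83-fold), Zfp503 (1.83-fold), Atp10a (1.9-fold) and Incenp (1.74-fold) rose, as did the promoters of Usp34, Pcgf5, Gpbp1 and Amz2 (log2 0.468 to 0.733). Peaks near Tnfsf18 (2.38-fold), Slc40a1, the iron exporter ferroportin (1.82-fold), Zeb1 (3.58-fold), Polr1a (2.31-fold) and Slc16a7 (3.19-fold) fell, as did peaks on chromosomes 15, 9 and 8 at 50108795, 31997570 and 14675316 (2.14-fold, 1.87-fold and 1.61-fold). The sorter differs between these groups. An additive model with the sorter put the Slc16a7 and chromosome 8 peaks at 0.466 and 0.202. These values are a common repopulation effect taken from the PP, PBP, LL and LBL libraries. They do not adjust PBL vs PL for the sorter, since the sorter term there takes up the PBL level. No list was called (adjusted p 0.235 to 0.988), and median and mean had opposite signs for border macrophage (-0.0349 and 0.0489) and neutrophil markers (0.0275 and -0.0299). Without PL 3_4 inflammatory and disease-associated loci were called higher (medians 0.15 and 0.134, adjusted p = 0.0152 and 0.0179), and without PL 1_2 astrocyte markers lower (-0.495, 0.0139). The medians of the first pair turned sign over left-out libraries (-0.028 to 0.15 and -0.052 to 0.134). Of the calls 74.2% were higher, against 58.6% with library sizes and 64% with cyclic loess offsets. The count was 1010 without PL 1_2, 11 without PL 3_4, 9, 15 and 2 without PBL 1_2, 3_4 and 4_5, 0 with DESeq2 and 2 with limma-trend.

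After LPS at both times, LBL vs LL, 19 peaks were called, 9 higher and 10 lower in LBL, and 13 loci, all higher. Beside Cd36, peaks near Fbn2 (2.88-fold), Ell2 (2.81-fold), Myo5a (5.52-fold), R3hcc1l (2.18-fold) and Slc16a10 (3.42-fold) and at chromosome 15, 5872142 (3.31-fold) rose. Peaks fell at the promoter of Egr1, an immediate early transcription factor (1.43-fold), and near Irf8, a transcription factor of the myeloid lineage (2.53-fold), Rcan1, a calcineurin regulator (2.56-fold), the glycolytic regulator Pfkfb3 (1.87-fold), Jmjd1c (2.39-fold), Foxn3 (3.84-fold), Ank2 (2.03-fold), Slc44a5 (2.83-fold), E230025N22Rik (1.87-fold) and Mid1 (1.44-fold). Immediate early and AP-1 loci had a median of -0.119 (adjusted p = 7.63e-08, and 0.07 with an estimated correlation), with none of 23 called and 5 lower adjusted over the list alone. Inflammatory loci had a median of -0.11 (adjusted p = 0.00878, and 0.718 with an estimated correlation), with none of 31 called and none adjusted over the list alone, and were not called without LL 1_2 (0.098) or LBL 1_2 (0.069) or within 1 kb (0.209). The other 15 lists had adjusted p between 0.234 and 0.918, with median and mean of opposite sign for neutrophil (0.0633 and -0.0558), astrocyte (-0.0901 and 0.0138) and endothelial markers (3.45e-05 and -0.0102). The count was 1 without LL 1_2, 1 without LL 3_4, 8 without LBL 1_2, 2 without LBL 3_4, 1 with DESeq2 and 2 with limma-trend.

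Microglia challenged at both times were also set against the PBS groups. In LL vs PP 2301 peaks were called, 1550 higher and 751 lower, and in LBL vs PBP 1809, 1479 higher and 330 lower. The Map3k8 promoter was 5.46-fold and 5.06-fold higher, and an intronic Zbtb16 peak on chromosome 9, 48723398 to 48723981, 7.98-fold and 7.59-fold higher (log2 3 ± 0.341 and 2.92 ± 0.313 SE). The Zbtb16 peak at 48744940 was 16.2-fold higher in LL vs PP (log2 4.02 ± 0.459, adjusted p = 1.32e-11). This fold rests on a level near the floor in PP, at 2.05 ± 0.0761 CPM, against 34.1 ± 3.02 CPM in LL (SD, n = 2 each). Peaks near Rbpj were 4.52-fold and 3.99-fold higher, near Tbc1d14 3.47-fold and 3.82-fold, and at chromosome 16, 93246704 and chromosome 9, 70284585 7.14-fold and 9.29-fold, and 3.8-fold and 4.36-fold. Other named rises in LL vs PP were near Il12a (5.16-fold) and at chromosomes 13 and 19, 107607161 and 21031643 (4.53-fold and 2.63-fold). In LBL vs PBP they were near Tbc1d2b (4.93-fold), Tma16 (5.02-fold) and 1700028I16Rik (3.84-fold) and at chromosome 12, 35799072 (2.75-fold).

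Named falls in LBL vs PBP included peaks near Mir146, a microRNA gene (2.17-fold), Smad7, an inhibitor of TGF-beta signalling (2.58-fold), Cbfa2t3 (2.74-fold), Pik3r4 (3.71-fold), Alg8 (2.25-fold), BC147527 (3.07-fold), Mid1 (1.62-fold) and Siglech (2.49-fold), and chromosome 18 and 7 peaks at 81751697 and 134555914 (3.26-fold and 3.3-fold). The 10 named falls in LL vs PP were 2.35-fold to 4.66-fold, with Mid1, Pak3, Cldn34d, 4931408C20Rik and G530011O06Rik among them, where PP also stood above PBP. In LL vs PP the inflammatory list (5 higher and 1 lower of 31, 8 and 1 adjusted over the list alone; adjusted p = 0.0021), negative regulators (6 of 25 higher, 7 adjusted over the list alone; 0.00403), disease-associated loci (3 of 27 higher, 5 adjusted over the list alone; 0.0021), immediate early and AP-1 loci (0.0189) and, downward, neuron markers (0.0189) were called. With an estimated correlation their adjusted p was 0.287, 0.119, 0.287, 0.287 and 0.287. In LBL vs PBP the inflammatory list (4 higher and 1 lower, 7 and 1 adjusted over the list alone; adjusted p = 0.00639), negative regulators (4 higher, 6 adjusted over the list alone; 0.00046), disease-associated loci (5 higher, 7 adjusted over the list alone; 0.00486) and border and bone-marrow-derived macrophage markers (5 of 18 higher, 7 and 1 lower adjusted over the list alone; 0.00146) were called upward, with adjusted p of 0.274, 0.0387, 0.274 and 0.212 at an estimated correlation. The other lists had adjusted p of 0.0589 to 0.86 in LL vs PP, where proliferation, neutrophil and astrocyte lists had median and mean of opposite sign, and 0.0903 to 0.881 in LBL vs PBP, where immediate early and astrocyte lists did. Over peaks within 1 kb none of the 5 lists of LL vs PP was called (0.163 to 0.321), nor were the inflammatory and disease-associated lists of LBL vs PBP (0.165 and 0.156). Without a library the immediate early list of LL vs PP (0.0927 without PP 1_2, 0.0502 without LL 1_2) and the inflammatory list of LBL vs PBP (0.0816 without PBP 3_4) lost their call. Interferon-stimulated (0.0208) and border macrophage loci (0.00847) of LL vs PP gained one without PP 1_2, and neuron markers of LBL vs PBP without PBP 1_2 (0.0171) or LBL 1_2 (0.0287). Among the list loci were Il4ra (1.83-fold and 1.67-fold), Socs3 (1.52-fold and 1.68-fold), Cd300lf (1.62-fold and 1.79-fold), F13a1 (2.89-fold and 2.62-fold) and Dab2 (1.86-fold and 1.47-fold), each called in both, while Nfkb2 was 1.46-fold and 1.48-fold lower. In LL vs PP 67.4% of the calls were higher, against 56.4% with cyclic loess offsets, and the count was 634 without PP 1_2, 716 without PP 3_4, 1329 without LL 1_2, 965 without LL 3_4 and 533 with DESeq2. In LBL vs PBP it was 620 without PBP 1_2, 953 without PBP 3_4, 989 without LBL 1_2, 878 without LBL 3_4 and 506 with DESeq2. All 20 named peaks of each were called with each library left out, while 22 of 30 named loci in LL vs PP and 16 of 26 in LBL vs PBP lost their call without some library, Nfkb2 in both and Dab2 in LBL vs PBP among them.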

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

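The tests of differences between the arms were set before the data were examined, the tests of the promoter-rich lower calls were chosen before their results were seen, except that the calls themselves were known, and the tests of the number of priming calls and, apart from isolation day, of PL 3_4 were chosen after. The LPS response differed between the repopulated and the undepleted arm at 28 peaks and 17 gene loci by a direct test of the difference, in which PBL alone was sorted on the XDP instrument, so that sorter and day cannot be separated from it. Of the 28 peaks, 14 lay at promoters, 4 at Mid1 and 6 on the X or Y chromosome, and 17 were lower in PL vs PP and not called in PBL vs PBP. Homeostatic microglia loci differed in their LPS response with a median of -0.249 (adjusted p = 0.00107, and 0.385 with an estimated correlation). Part of this difference lies between the PBS groups. Without LPS the list had a median of 0.186 in PBP vs PP (camera adjusted p = 0.303 with an estimated correlation). It was not called in PBL vs PL. The priming effect differed between the arms for inflammatory loci with a median of -0.112 (adjusted p = 0.0103, and 0.73 with an estimated correlation), a call lost without PL 1_2 (median -0.0435, adjusted p = 0.588), PBL 3_4 (0.0698), LL 1_2 (0.0544) or LBL 1_2 (0.0595) and over peaks within 1 kb (0.194). It also differed for immediate early and AP-1 loci with a median of -0.183 (adjusted p = 2.39e-05, and 0.184 with an estimated correlation).

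PL 3_4 stands apart from PL 1_2 and moves the counts of each comparison that uses PL. Isolation day separates these pools as it separates PP from PBP. The difference between the pools correlated with PP minus PBP at -0.161 (SE 0.014 over chromosomes left out). A day effect as the only source of both differences would give a positive value, which was not seen. PP minus PBP also holds the effect of repopulation, so this correlation cannot exclude isolation day. A larger share of signal in distal peaks stays open: among peaks that did not move in PBL vs PBP the difference was higher at distal than at promoter peaks by 0.266 (bootstrap SE 0.012), which restates the promoter shares of 53.2% and 58% of these libraries and is no separate evidence. A larger LPS response in this pool stays open, with a correlation of 0.0963 (SE 0.006) with the PBL vs PBP fold changes and a median difference of 0.209 over peaks higher there and 0.0429 over peaks lower there.

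The peaks lower in PL vs PP were rich in promoters, and so were those lower in LL vs PP (53.9%, 95% interval 50.3 to 57.5, adjusted p = 1.54e-21 by Fisher's exact test), while those lower in PBL vs PBP were not (17%). Lower depth of the PP libraries is excluded as the cause, since the promoter share was 65.9% after thinning to equal totals, against 40.4% of all tested peaks. Within PL vs PP the PL 3_4 library fits, since the share was 33.9% without it, against 36.7% of tested peaks, and 74.4% without PL 1_2. It cannot account for LL vs PP, which uses no PL library, and what the PP libraries common to both comparisons contribute beyond depth was not tested, apart from shares of 61.4% and 60.8% in PL vs PP without PP 1_2 and PP 3_4. A response common to both arms stays open: the 640 promoter peaks had a median of -0.107 (bootstrap SE 0.012) in PBL vs PBP, where 45 were called lower.

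More peaks were called for priming after repopulation (713) than without depletion (24). The additional PBL library is excluded as the whole cause, since with 1 PBL library left out the lowest count was 334, still above 24. That count is below 713, so a contribution of library number is not excluded. The closeness of the LBL pair, with a chi-square per degree of freedom of 0.994, was not tested as a cause. The count fell further without either LBL library and with the LBL libraries averaged, as given above. The spread of the PL pair stays open, with 304 calls without PL 1_2 and 6 without PL 3_4. A larger priming effect after repopulation also stays open: 6.92% of peaks had an unadjusted p under 0.05 in the direct test of the difference, and 0 were called. Isolation day cannot be separated from priming in either arm, nor can the sorter in LL vs PL.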

How the results depend on the processing

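Unrounded counts, read ends, isolation day as a term, thinning, the peaks without X and Y, and the averaged LBL libraries were chosen after the data were seen. The counts that follow are of pairs of a called item and an alternative. Direction and side of the threshold were kept in 272 list, 902 locus, 2773 peak and 6 promoter-share pairs. A peak or locus without an adjusted p under an alternative was counted as kept. The call was lost in 63 list, 293 locus and 568 peak pairs. Direction reversed in 4 locus pairs, from Fosl2 and Siglech, and in 2 peak pairs. The peak pairs are PBL vs PL peaks under the additive sorter model, whose repopulation effect does not use the PL or PBL level. Among pairs of an item not called and an alternative, 33 list and 7 locus pairs passed the threshold. The cause was not tested for the changes given here, except that a fold minimum added to the same test can only lower a count, and low depth, at 927840 counts for the smallest library, limits what can be called. DESeq2 size factors, library size, unrounded counts and no filter left each count of calls within a factor of 1.5. Where a library left out leaves 1 in a group, that library is assumed to vary like the others.

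With a minimum absolute log2 fold change of 1 the counts were 1350 for PL vs PP, 1944 for PBL vs PBP, 338 for LBL vs PBL, 34 for PBP vs PP, 11 for PBL vs PL, 1206 for LL vs PP and 1148 for LBL vs PBP, and the shared sign of the LPS response was 91.1%. DESeq2 called 808, 1213, 17, 9, 0, 533 and 506 in the same order, 0 for LL vs PL, 1 for LBL vs LL and 0 for the difference in LPS response, with shared signs of 100% for priming and 92.2% for LPS. Limma-trend called 4288 for PL vs PP, 4 for LL vs PL, 263 for LBL vs PBL, 421 for PBP vs PP, 2 for PBL vs PL, 2 for LBL vs LL and 52 for the difference in LPS response (shared sign 81.6%). A fit to the compared groups gave 1623, 3, 132 for PBP vs PP, 1 for PBL vs PL, 94 for LBL vs LL and 15 for the difference in LPS response (80% and 90.3%). Isolation day as a term gave 5090 for PL vs PP and 815 for PBP vs PP, with the day effect taken from the PL pair alone. Thinning gave 1836, 1837, 0 for LL vs PL, 122 for LBL vs PBL, 0 for PBL vs PL, 4 for LBL vs LL, 1307 for LL vs PP, 858 for LBL vs PBP and 1 for the difference in priming (77%). The stricter filter gave 15 for LL vs PL and 18 for PBL vs PL, and loess offsets 44 for the difference in LPS response. Read ends gave 6 for LL vs PL, 137 for PBP vs PP, 2 for PBL vs PL and 9 for LBL vs LL (83.2%). Without X and Y peaks PBP vs PP had 34 and the difference in LPS response 11. With the LBL libraries averaged LBL vs PBL had 23, LBL vs LL 1 and LBL vs PBP 689. The additive sorter model gave 1120 for a priming effect common to both arms, an estimate in which the PL level cancels out. It gave 45 for LBL vs LL, as a repopulation effect common to all states of challenge that uses neither the PL nor the PBL level. That effect was 0.466 and 0.202 at the Slc16a7 and chromosome 8 peaks, opposite in sign to PBL vs PL. The model was not run for shared signs and differences between arms.

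Replicate differences had little in common between groups, with correlations between -0.0174 and 0.166 over 15 pairs of groups, the highest for PL with PBL. This cannot exclude a pairing by replicate number, since differences that are mostly noise would correlate little in either case. With the replicate block LL vs PL had 49 peaks and 13 loci, LBL vs PBL 472 peaks, PBP vs PP 107 peaks and 82 loci, LBL vs LL 37 peaks and 23 loci, the difference in LPS response 123 peaks and 146 loci and that in priming 1 locus (81.4% for LPS); the inflammatory list of LL vs PL was called (-0.0753) and the border macrophage list of LBL vs PBL was not (0.267).

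Loci over peaks within 1 kb gave 825 for PL vs PP, 328 for PBL vs PBP, 2 for LL vs PL, 28 for LBL vs PBL, 0 for PBL vs PL, 0 for LBL vs LL and 49 for the difference in LPS response, and reversed Fosl2 and Siglech in PL vs PP (-0.00875 and 0.0447) and Siglech in LL vs PP (0.307). Within 10 kb there were 109 for LBL vs PBL, 10 for PBP vs PP, 16 for PBL vs PL and 2 for LBL vs LL, and Siglech in LL vs PP reversed (0.176).

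With a library left out peak counts ran from 681 to 5109 for PL vs PP, 1732 to 3453 for PBL vs PBP, 5 to 304 for LL vs PL, 88 to 598 for LBL vs PBL, 10 to 29 for PBP vs PP, 2 to 1010 for PBL vs PL, 1 to 8 for LBL vs LL, 634 to 1329 for LL vs PP, 620 to 989 for LBL vs PBP, 0 to 1037 for the difference in LPS response and 0 to 71 for that in priming. Shared signs ran from 72.6% to 89.8% and 78.2% to 94.1%, and the medians of LPS-opened peaks from -0.203 to -0.00431 in LL vs PL and -0.0746 to -0.00143 in LBL vs PBL. Locus counts ran from 343 to 2829, 523 to 931, 0 to 243, 18 to 116, 4 to 10, 5 to 946 and 2 to 5 for the first 7 comparisons, and 0 to 1159 and 0 to 107 for the differences.

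The estimated correlation leaves a list's median as it is and ended the calls of these lists: PL vs PP (inflammatory 0.337, interferon 0.195, negative regulator 0.22, disease-associated 0.185), PBL vs PBP (immediate early 0.0676, disease-associated 0.0874), LL vs PL (interferon -0.155), LBL vs PBL (inflammatory -0.221, immediate early -0.0883, border macrophage 0.186), PBP vs PP (homeostatic 0.186), LBL vs LL (inflammatory -0.11, immediate early -0.119), LL vs PP (inflammatory 0.273, negative regulator 0.0849, immediate early 0.16, disease-associated 0.221, neuron -0.38), LBL vs PBP (inflammatory 0.186, disease-associated 0.0774, border macrophage 0.256), difference in LPS response (homeostatic -0.249), difference in priming (inflammatory -0.112, immediate early -0.183). Peaks within 1 kb ended those of PL vs PP (negative regulator 0.0259, disease-associated 0.0906), PBL vs PBP (disease-associated 0.0246), PBP vs PP (homeostatic 0.128), LBL vs LL (inflammatory -0.0796), LL vs PP (inflammatory 0.0958, negative regulator 0.0436, immediate early 0.189, disease-associated 0.16, neuron -0.343), LBL vs PBP (inflammatory 0.0907, disease-associated 0.07), difference in priming (inflammatory -0.0898), and brought calls in PBL vs PBP (interferon 0.219), LL vs PL (inflammatory -0.129), LBL vs PBL (interferon -0.153), LBL vs PBP (neutrophil 0.161). Peaks within 10 kb ended those of PL vs PP (disease-associated 0.201), PBL vs PBP (disease-associated 0.0762), LBL vs PBL (border macrophage 0.0698), LL vs PP (neuron -0.366), and brought calls in PBL vs PBP (interferon 0.171), LL vs PL (inflammatory -0.0797), LBL vs PBP (neutrophil 0.19). Library size brought calls in LL vs PL (inflammatory -0.0849), PBP vs PP (interferon 0.127, neuron -0.354), LL vs PP (border macrophage 0.102). With a library left out the medians of lists whose call changed ran as follows: PL vs PP (interferon 0.164 to 0.393, negative regulator 0.0987 to 0.222, homeostatic -0.126 to 0.0326, disease-associated 0.0528 to 0.346, neuron -0.361 to -0.111), PBL vs PBP (interferon 0.0963 to 0.195, immediate early 0.0577 to 0.101, disease-associated 0.0581 to 0.13, border macrophage 0.0782 to 0.174), LL vs PL (inflammatory -0.137 to 0.0346, interferon -0.217 to -0.0805, disease-associated -0.0595 to 0.13), LBL vs PBL (interferon -0.0846 to 0.0184, border macrophage 0.136 to 0.268, neuron -0.352 to 0.0451), PBP vs PP (interferon 0.0983 to 0.19, neuron -0.41 to -0.257), PBL vs PL (inflammatory -0.028 to 0.15, disease-associated -0.052 to 0.134, astrocyte -0.495 to -0.0447), LBL vs LL (inflammatory -0.14 to -0.0773), LL vs PP (interferon 0.0203 to 0.187, immediate early 0.105 to 0.177, border macrophage 0.0545 to 0.303), LBL vs PBP (inflammatory 0.131 to 0.138, neuron -0.453 to -0.0351), difference in LPS response (inflammatory 0.0297 to 0.158), difference in priming (inflammatory -0.231 to -0.0435).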

Other observations

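The glucocorticoid loci were listed after Zbtb16 had been seen among the peaks raised most in LL vs PP, and the prediction for the other loci was written before their test. Metallothionein genes, which encode metal-binding stress proteins and lie outside the naming rule used above, responded in both arms. Mt2 rose by 1.51 ± 0.175 (SE) on the log2 scale in PBL vs PBP (adjusted p = 7.94e-10) and by 0.773 ± 0.19 in PL vs PP (0.00364), and fell by 0.884 ± 0.152 in LBL vs PBL (0.000219). Mt1 rose by 0.702 ± 0.103 and 0.546 ± 0.12 in the LPS comparisons. Hif3a, a hypoxia-inducible factor subunit, rose by 0.479 ± 0.119 and 0.779 ± 0.144, Rcan1 by 0.562 ± 0.0916 and 0.54 ± 0.105, and Tgm2, a transglutaminase, by 0.47 ± 0.093 and 0.385 ± 0.111. Klf9, Fkbp5 and Cdkn1a rose in PBL vs PBP (0.725 ± 0.121, 0.456 ± 0.0863 and 0.665 ± 0.14) and were not called in PL vs PP (0.314, 0.22 and 0.0462), and Tsc22d3 rose in PL vs PP (0.568 ± 0.124) and was not called in PBL vs PBP (-0.0902). The direct test of the difference between the arms called none of these 4 loci (0.411 ± 0.191, 0.236 ± 0.132, 0.619 ± 0.218 and -0.658 ± 0.159, adjusted p = 0.308, 0.418, 0.166 and 0.0564).

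A hypothesis from these values is that systemic LPS raises glucocorticoids and that their receptor opens its targets in microglia, since Zbtb16, Fkbp5, Tsc22d3, Klf9 and the metallothioneins are known targets. Of 24 listed target genes 20 were measured, 5 of them also in the lists fixed before. Without Zbtb16, the 19 others were raised in PBL vs PBP with a median of 0.251, with 8 higher and 1 lower. In PL vs PP their median was 0.143, with 6 higher and 1 lower. Other listed targets did not rise in either: Per1, Sgk1, Arrdc2 and Map3k6 were at -0.142, -0.114, -0.0368 and -0.0178 in PL vs PP. In PBL vs PBP they were at -0.0176, -0.204, -0.0428 and -0.0167, and none of these was called. The camera p with an estimated correlation, not adjusted over the comparisons tested, was 0.00239 and 0.0414. In PBP vs PP, without LPS, their median was -0.109 (camera p = 0.0565 with an estimated correlation). A lower level in PBP may thus add to the rise in PBL vs PBP, groups that also differ in sorter and day. The test fits the hypothesis and does not separate glucocorticoids from other signals that reach the same loci, and no hormone level was analysed here. Mertk, also a known target, fell in both (-0.517 ± 0.0951 and -0.781 ± 0.112), and the Zbtb16 locus as a whole was not called (0.4 ± 0.178 and 0.504 ± 0.205).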
